A study of Mus musculus with 6 samples.

How the data were processed

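Poly(A)-selected RNA of sorted naive CD4 T cells from mouse lymph nodes was made into libraries with the TotalScript kit, per the labels' protocols. The 6 libraries were grouped by title and source name as 3 control and 3 S1pr1-null. The deposited values were FPKM per gene symbol, 1 table per library, made by the authors with STAR and Cufflinks against mm10 (GRCm38), per the submitters' processing notes. Tool versions, the gene annotation and the Cufflinks normalization option are not given in the sources used here. Each table held 17577 symbols with none duplicated, and the same symbols were in all 6, so the rules for duplicated or unlisted symbols changed nothing. The gene column of all 6 tables was headed Bcl2Tg_Ctrl_1, a name that is in no label, and its values were gene symbols. The value column of each unnumbered library carried the number 4 in its header, and these libraries are called unnumbered here, as in their titles.

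FPKM are not counts, so the total depth is unknown and no count model was used. Relative depth was estimated from the ratio to the unnumbered control that recurred most often among genes under 1 FPKM. That ratio held for 51 to 77 of 2057 to 2878 genes, against a mean of 2.1 to 3.5 genes per ratio bin around it. It gave relative depths of 0.595 (library labelled control 1), 1.181 (control 3), 1.058 (unnumbered S1pr1-null), 0.756 (S1pr1-null 1) and 0.831 (S1pr1-null 3). The same ratios came from short RNA genes, and the ratio between S1pr1-null 1 and the library labelled control 1 was 0.787 both directly and through the reference. A shallow library has a larger error for low genes. Short RNA genes (microRNA, small nucleolar and related genes, 423 listed) took 14.7 to 44.2% of the summed FPKM, most in the library labelled control 1 (44.2%) and S1pr1-null 1 (32.3%). The gene Mir6236 alone took 27.86% and 18.77% in these 2 and 0.69 to 1.94% in the others. Short RNA genes were picked by symbol, and the ribosomal RNA precursor Rn45s, which is not short, is counted among them. It had 11361.4 FPKM in the library labelled control 1 and 2228.9 to 3603.7 FPKM in the other libraries.

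Genes with a mean of at least 1 FPKM over the 6 libraries were tested (9700, of which 299 were short RNA genes). Group differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(FPKM + 1), without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Gene lists (48 lists written before the data were examined) were tested with limma's camera on the same values with a preset correlation of 0.01, adjusted over the 44 lists with at least 3 tested members. S1pr1 was left out of each list, and camera with an estimated correlation and fry were run beside it. Lists share members, so their tests are not independent. Lists of S1P receptors (2 tested members), mitochondrially encoded genes (0), stromal and endothelial markers (1) and gamma delta and NKT markers (0) had too few members. The planned share of mitochondrially encoded transcripts was not analysed here, since no symbol of that genome is among those listed. Single comparisons used exact permutation tests, which cannot go below 0.1 for 3 against 3 when two-sided.

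The genes named were set by a rule written before the data were examined: S1pr1, then up to 12 genes in each direction, first those past the adjusted threshold with groups that do not overlap, and then those with the smallest unadjusted p and groups that do not overlap. Predicted genes, pseudogenes, antisense, microRNA, small nucleolar RNA and receptor segment genes were counted but not named by that rule. For each list described, the members with the smallest unadjusted p were named, or the 2 most abundant where the list did not pass. Other named genes were chosen after their values were seen.

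The fit was tested on simulated data with the means of the 9700 genes, 200 of them changed. With the spread of these libraries it recovered 0% at a log2 change of 1, 36% at 2 and 82.5% at 3, with at most 11 false calls. With a spread of 0.25 it recovered 93% at a change of 1 and 100% at 2 and 3. Gene locations came from GENCODE M21 on GRCm38, in which 98.7% of the symbols were matched. Alternatives covered the pseudocount, the filter, 3 rescalings, limma's settings, library weights, a block by the number in the title, and leaving out each library in turn. Alternatives chosen after seeing the data left out short RNA genes, added a term for the division of the libraries, or left out 2 or 3 libraries together. Python 3 scripts joined the tables and drew the figures.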

Results

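The series measured poly(A) RNA of naive CD4 T cells from mouse lymph nodes with and without the sphingosine-1-phosphate receptor S1pr1, the receptor through which lymphocytes sense the lipid signal that draws them out of lymphoid organs. The cells came from mixed bone marrow chimeras, in which marrow of floxed S1pr1 mice with a tamoxifen-inducible Cre, or of littermate controls, developed beside wild-type marrow in the same host, so that the comparison asks which transcripts change within the cell that lost the receptor. Donor-derived cells were sorted as CD62L-high and CD44-low after tamoxifen. There were 6 libraries, 3 control and 3 S1pr1-null, and each group held a library with no number in its title, a library numbered 1 and a library numbered 3. Values were in FPKM, fragments scaled by transcript length and by the mapped fragments of the library, for 17577 genes, of which 9700 had a mean of at least 1 FPKM and were tested. Total depth was not given, and the ratios between libraries that recurred most often among low values gave depths of 0.595 to 1.181 relative to the unnumbered control. Nothing in the labels says whether the libraries of a group came from separate chimeras, so the p-values measure the spread between these libraries.

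S1pr1 lay far below the unnumbered control and control 3 in all S1pr1-null libraries, and it was similarly low in 1 library of the control group. It measured 163.9 FPKM in the unnumbered control and 214.2 FPKM in control 3. The S1pr1-null libraries had 14.5 FPKM in the unnumbered one, 4.30 FPKM in number 1 and 11.4 FPKM in number 3. S1pr1-null 1 also had low Klf2, a transcription factor that drives S1pr1 (8.20 FPKM, 48.2% of the lowest other library). Its low S1pr1 therefore does not by itself show the deletion. The library labelled control 1 had 10.1 FPKM, inside the S1pr1-null range. The group means were 129 ± 106 FPKM for the controls and 10.1 ± 5.23 FPKM for the S1pr1-null libraries (SD, n = 3 each). The difference was -2.87 ± 1.08 on the log2(FPKM + 1) scale (SE), with a limma adjusted p of 0.9999 and an exact permutation p of 0.3 (two-sided; 3 against 3 allows 0.1 at best). Leaving out the library labelled control 1 moved the difference to -4.23, still short of the threshold with an adjusted p of 0.191. S1pr1 lies on chromosome 3 from 115710433 to 115715072 on the minus strand (GRCm38). The labels do not say which part of the gene was floxed, so the remaining signal can include transcripts of the deleted allele. Each direction drawn below includes the library labelled control 1 among the controls. Of the other receptors for the same ligand, S1pr4 had 29.9 to 62.0 FPKM in the controls and 34.0 to 47.3 FPKM in the S1pr1-null libraries, and S1pr2 had 1.09 to 1.91 FPKM in the controls and 1.10, 12.3 and 2.03 FPKM in the unnumbered S1pr1-null library, S1pr1-null 1 and S1pr1-null 3.

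**Figure D1:**
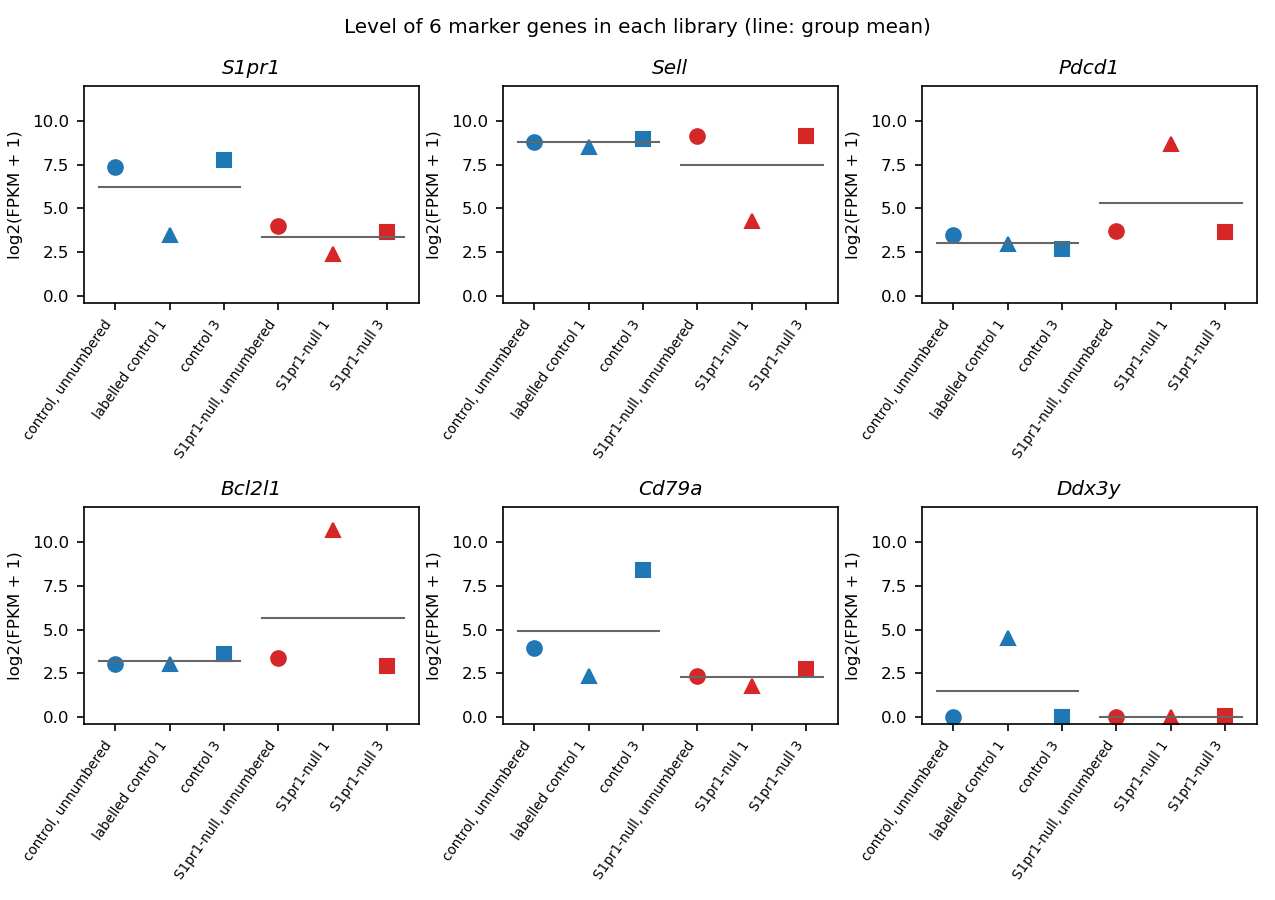
Level of S1pr1, Sell, Pdcd1, Bcl2l1, Cd79a and Ddx3y in each library as log2(FPKM + 1) on the vertical axis, with 1 point per library (blue control, red S1pr1-null) and a line at each group mean. The library labelled control 1 sits with the S1pr1-null libraries for S1pr1 (10.1 FPKM) and is the library with Ddx3y at 21.7 FPKM, S1pr1-null 1 stands apart for Sell, Pdcd1 and Bcl2l1, and control 3 for Cd79a.

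No protein-coding gene passed the threshold in either direction. With limma on log2(FPKM + 1), 0 genes were higher and 2 were lower in the S1pr1-null libraries at a Benjamini-Hochberg adjusted p under 0.05. An unadjusted p under 0.05 was reached by 133 of 9700 genes, fewer than that threshold lets through by chance in as many independent tests. Other splits of the 6 libraries into 3 and 3 had from 103 to 2814 such genes. The 2 lower genes are microRNA genes, named here after their values were seen. Mir7046 (chromosome 7, 24970010 to 24970075, in an intron of Rabac1) had 141.1, 474.5 and 119.5 FPKM in the unnumbered control, the library labelled control 1 and control 3, was listed at 0 in all 3 S1pr1-null libraries, and had an adjusted p of 0.00854. Mir677 (chromosome 10, 128085286 to 128085363, in an intron of Atp5b and annotated as both a microRNA and a small nucleolar RNA) had 52.8, 266.0 and 89.4 FPKM in the same controls, 0 in the S1pr1-null libraries and an adjusted p of 0.0181. Both genes are under 100 bp long, and their control values are whole multiples (1, 2 and 1 for Mir7046, and 1, 3 and 2 for Mir677) of the smallest step seen once relative depth is taken out. If that step is 1 fragment, these FPKM values rest on 1 to 3 fragments per control library. The RNA was poly(A)-selected and both genes lie in introns, so the values cannot be read as levels of the mature microRNAs. Neither adjusted p stayed under 0.05 with a pseudocount of 5 (0.11 for Mir7046 and 0.259 for Mir677), without a filter on low values (0.339 and 0.429), or with the division of the libraries described below as a term (0.0599 and 0.0648). The listed FPKM values are the same in each. Mir677 also missed the threshold without control 3 (adjusted p = 0.0977), without the unnumbered S1pr1-null library (0.096) and without S1pr1-null 3 (0.0546). Of the 9700 genes, 477 (4.92%) had groups that did not overlap, where chance gives 10%. In simulations with the spread of these libraries, 0% of 200 genes changed by 1 log2 unit, 36% of those changed by 2 and 82.5% of those changed by 3 were recovered among 9700 genes, so changes of 1 log2 unit in single genes were not detectable at this spread.

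Among genes that did not pass and that the naming rule covers, Id2, an inhibitor of E protein transcription factors, had the smallest unadjusted p of those higher in all 3 S1pr1-null libraries. It had 71.0 ± 25.6 FPKM in the controls and 211.4 ± 28.0 FPKM in the S1pr1-null libraries (SD, n = 3 each), a log2 difference of 1.62 ± 0.34 (SE). Folr4 (now Izumo1r), a surface protein of regulatory and follicular T cells, had 145.9 ± 5.51 FPKM against 420.6 ± 190.2 FPKM, and 2 of its S1pr1-null values, 297.2 and 325.0 FPKM, lay close together with the third, 639.7 FPKM, in S1pr1-null 1. Pink1, the kinase that marks damaged mitochondria for removal, had 4.14 ± 1.80 FPKM in the controls and 13.4 ± 4.19 FPKM in the S1pr1-null libraries, a log2 difference of 1.51 ± 0.39 (SE). Bad, a pro-apoptotic BCL2 family member, had 11.5 ± 1.86 FPKM against 20.9 ± 1.49 FPKM. Casp1, the inflammasome protease, had 7.14 ± 3.49 FPKM against 38.1 ± 31.4 FPKM, with 73.7 FPKM in S1pr1-null 1. Sec11c, a subunit of the signal peptidase, had 79.2 ± 17.9 FPKM in the controls and 145.5 ± 12.7 FPKM in the S1pr1-null libraries. Ubl3 had 24.0 ± 3.92 FPKM against 42.9 ± 5.63 FPKM, and the noncoding AW112010 had 342.4 ± 134.4 FPKM against 732.3 ± 107.3 FPKM. Lower-level genes of the same kind were Fam110a (3.20 ± 1.16 against 9.88 ± 2.81 FPKM), Ncmap (7.79 ± 4.40 against 25.9 ± 11.1 FPKM) and Apol9b (7.70 ± 6.48 against 28.5 ± 6.45 FPKM). Tmod1, a cap of actin filaments, had 0.959 FPKM in the unnumbered control, near 0 in the other controls, and 3.62, 1.98 and 5.96 FPKM in the S1pr1-null libraries. All 12 had an adjusted p of 0.9999.

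Of the genes that the naming rule covers, those lower in all 3 S1pr1-null libraries were led by Slc16a5, a monocarboxylate transporter. Mir7046 and Mir677, outside that rule, had smaller unadjusted p. Slc16a5 had 22.1 ± 3.65 FPKM in the controls and 6.09 ± 3.50 FPKM in the S1pr1-null libraries (SD, n = 3 each), a log2 difference of -1.84 ± 0.46 (SE). Klf7, a Kruppel-like transcription factor, had 17.1 ± 1.80 FPKM against 8.18 ± 2.91 FPKM. Prf1, which encodes the pore-forming protein perforin, had 25.9 ± 5.72 FPKM in the controls and 14.1 ± 2.83 FPKM in the S1pr1-null libraries. Cnr2, a cannabinoid receptor, had 8.08 ± 2.15 FPKM against 3.52 ± 1.14 FPKM. Rapgef4, an exchange factor for Rap GTPases, had 7.15 ± 0.54 FPKM against 2.79 ± 1.68 FPKM. Klhdc1 had 10.3 ± 3.64 FPKM in the controls and 3.44 ± 0.29 FPKM in the S1pr1-null libraries, and Usp28, a deubiquitinase, had 11.1 ± 3.36 against 4.15 ± 1.77 FPKM. Gatc, which serves mitochondrial translation, had 11.8 ± 3.66 against 4.97 ± 1.53 FPKM, and Cdk5rap1, which modifies transfer RNA, had 12.1 ± 9.10 against 1.97 ± 2.76 FPKM with 22.6 FPKM in control 3. Tsr1, a ribosome assembly factor, had 28.7 ± 13.8 against 12.8 ± 2.24 FPKM. Fcgrt, the neonatal Fc receptor, had 6.20 ± 5.79 against 0.771 ± 0.524 FPKM, with 12.9 FPKM in control 3, and Atp8b4 had 4.82 ± 1.93 against 1.38 ± 0.97 FPKM. These 12 also had an adjusted p of 0.9999.

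**Figure D2:**
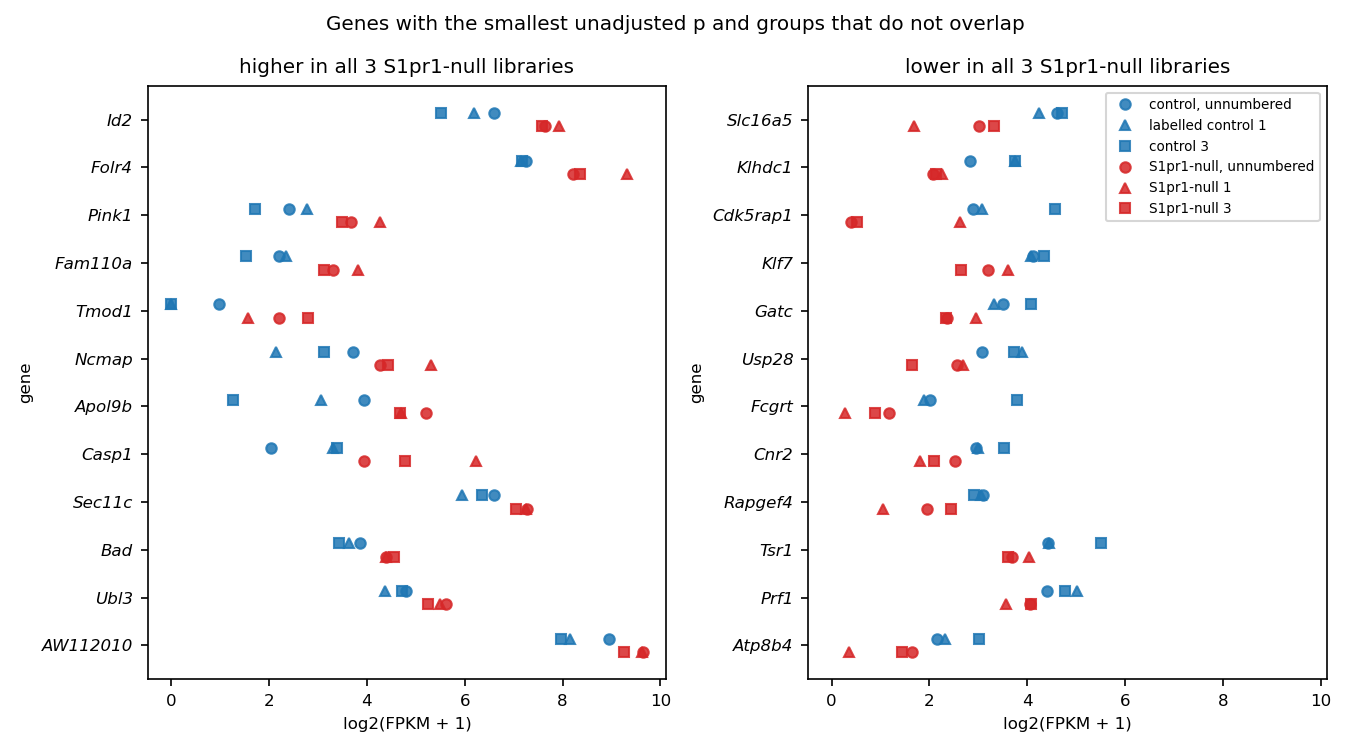
Level of the 12 genes higher and the 12 lower in all 3 S1pr1-null libraries with the smallest unadjusted p, as log2(FPKM + 1) on the horizontal axis, with 1 point per library (blue control, red S1pr1-null, shape by the number in the title). Predicted genes, pseudogenes, antisense, microRNA, small nucleolar RNA and receptor segment genes were left out of this choice. Id2 runs from 45.0 to 96.3 FPKM in the controls and from 191.0 to 243.4 FPKM in the S1pr1-null libraries, and no gene shown passed the adjusted threshold.

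Transcripts of non-naive CD4 T cells were higher in the S1pr1-null group, and this followed S1pr1-null 1. Of 44 lists tested, 10 passed camera with its preset correlation, 7 higher and 3 lower, none of them with an estimated correlation (smallest adjusted p = 0.979) or with fry (smallest adjusted p = 0.989). No member of any list passed over all genes, and 1 gene, Id2 in the memory and effector list, passed adjusted over the list alone. Regulatory T cell markers were higher as a list (15 of 15 members higher, mean log2 difference 1.29, camera adjusted p = 1.08e-08; 0.979 with an estimated correlation), with Tnfrsf4 at 10.7 to 105.7 FPKM in the controls and 77.6, 278.8 and 114.1 FPKM in the S1pr1-null libraries, Il2ra, a chain of the interleukin-2 receptor, at 2.06 to 18.1 FPKM against 12.99, 36.5 and 34.9 FPKM, and Folr4 as above. Follicular helper markers (10 of 10 higher, mean 1.34, adjusted p = 6.17e-05; 0.979 with an estimated correlation) included Pdcd1, the inhibitory receptor PD-1, at 5.23 to 10.04 FPKM in the controls and 11.8, 402.4 and 11.5 FPKM in the S1pr1-null libraries, Icos at 20.5 to 25.8 FPKM against 33.9, 139.0 and 30.3 FPKM, and Sh2d1a, an adaptor of SLAM receptors, at 69.5 to 145.5 FPKM against 159.6, 246.1 and 187.3 FPKM. Memory and effector markers were higher in 20 of 25 (mean 0.80, adjusted p = 4.24e-04; 0.993 with an estimated correlation), with Maf at 0.976 to 2.26 FPKM in the controls and 3.02, 73.2 and 5.50 FPKM in the S1pr1-null libraries, beside Id2 and the lower Prf1. Naive T cell identity genes were lower in 18 of 23 (mean -0.51, adjusted p = 2.20e-03; 0.979 with an estimated correlation), with Foxp1 at 58.4 to 69.4 FPKM against 37.0 to 55.5 FPKM, Foxo1 at 21.2 to 32.5 FPKM against 13.8 to 23.6 FPKM and Tdrp at 16.4 to 42.5 FPKM against 4.80 to 20.7 FPKM.

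S1pr1-null 1 differed from the other libraries in the transcripts of the sort markers. Sell, which encodes CD62L, had 17.9 FPKM there and 366.5 to 563.2 FPKM in the other 5 libraries, and Cd44 had 38.7 FPKM against 4.71 to 6.54 FPKM. Its mean deviation from the 6-library mean was 2.30 for the regulatory, 3.21 for the follicular helper and 2.28 for the memory list, and -1.14 for the naive list. Without it, the memory list turned to -0.125 (adjusted p = 0.744), and the follicular helper list (mean 0.079) and the naive list (mean -0.063) no longer passed. The regulatory list still did at a mean of 0.538 (camera adjusted p = 0.00175 at the preset correlation). Without the library labelled control 1, the naive mean was -0.453 (adjusted p = 0.0825) and the memory mean 0.587 (adjusted p = 0.0987), not past the threshold. The memory mean was 1.276 without the unnumbered S1pr1-null library and 1.25 without S1pr1-null 3. Without S1pr1-null 1 together with the library labelled control 1 and control 3, chosen after seeing the data, the regulatory list had a mean of -0.042. The unnumbered control was then the only control left. Its deviation for that list was -0.13, above those of the library labelled control 1 (-0.86) and control 3 (-0.944), so leaving these out moves the mean down.

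B cell markers were lower as a list in the S1pr1-null group (20 of 20 members lower, mean log2 difference -1.51, camera adjusted p = 6.35e-07; 0.993 with an estimated correlation), and all 20 were highest in control 3. Cd79a, a chain of the B cell receptor complex, had 336.7 FPKM there, 14.5 FPKM in the unnumbered control, 4.11 FPKM in the library labelled control 1 and 2.40 to 5.62 FPKM in the S1pr1-null libraries. Ms4a1, which encodes CD20, had 182.9 FPKM in control 3 and at most 3.51 FPKM elsewhere, and Fcer2a had 94.3 FPKM and at most 1.02 FPKM elsewhere. Without control 3 the list mean was 0.377 (adjusted p = 0.466), and without the library labelled control 1 it was -2.694. Myeloid and dendritic cell markers were higher in 6 of 7 tested members (mean 0.44, camera adjusted p = 0.0268; 0.979 with an estimated correlation). Of 28 listed genes only these 7 reached a mean of 1 FPKM, so the list says little about myeloid cells. Tyrobp had 0.858 to 1.37 FPKM in the controls and 6.68, 2.03 and 1.84 FPKM in the S1pr1-null libraries. Cst3 had 69.2 to 155.2 FPKM against 123.5 to 176.9 FPKM and Ctss 182.6 to 288.4 FPKM against 251.8 to 335.3 FPKM. The mean of that list was 0.159 without the library labelled control 1 (adjusted p = 0.747). It was 0.396 without the unnumbered S1pr1-null library (adjusted p = 0.223) and 0.374 without S1pr1-null 1 (adjusted p = 0.0597), near the full value but not past the threshold.

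Lists of oxidative phosphorylation and of the mitochondrial ribosome were slightly higher in the S1pr1-null group, while the other lists of nuclear genes of the mitochondrion did not pass. For oxidative phosphorylation, 69 of 79 members were higher with a mean log2 difference of 0.23 (camera adjusted p = 4.97e-03; 0.993 with an estimated correlation), and for the mitochondrial ribosome 62 of 77 were higher with a mean of 0.21 (adjusted p = 2.20e-03; 0.993 with an estimated correlation). Members with the smallest unadjusted p were Mrps6, at 11.3 to 22.9 FPKM in the controls and 27.8 to 42.8 FPKM in the S1pr1-null libraries, Mrps35, at 5.90 to 20.2 FPKM against 20.7 to 33.0 FPKM, Mrps12, at 27.0 to 48.5 FPKM against 33.3 to 70.1 FPKM, Ndufab1, at 19.4 to 20.7 FPKM against 22.4 to 32.9 FPKM, and Atpif1, an inhibitor of the ATP synthase, at 20.5 to 85.5 FPKM against 56.2 to 70.9 FPKM. Ndufs5 went the other way, with 2.13 to 4.88 FPKM against 1.07 to 3.12 FPKM. Both lists followed a division of the libraries that crosses the groups: the oxidative phosphorylation list deviated by 0.45, 0.43 and 0.42 in the unnumbered control, the unnumbered S1pr1-null library and S1pr1-null 3, and by -0.53, -0.26 and -0.50 in the library labelled control 1, control 3 and S1pr1-null 1. With that division as a term, chosen after seeing the data, the oxidative phosphorylation mean was -0.066 (adjusted p = 0.00226, lower relative to other genes), and the mitochondrial ribosome no longer passed (adjusted p = 0.261). Both p-values are from camera at the preset correlation of 0.01. The estimated correlation of the oxidative phosphorylation members was 0.584, so 0.00226 overstates the evidence. Neither list passed on leaving out any 1 of 4 libraries. The oxidative phosphorylation mean was then 0.021 without the library labelled control 1, 0.154 without control 3, 0.072 without the unnumbered S1pr1-null library and 0.077 without S1pr1-null 3. The mitochondrial ribosome mean was, in the same order, 0.075, 0.151, 0.119 and 0.118. Both were larger without the unnumbered control (0.509 and 0.406) or S1pr1-null 1 (0.535 and 0.394). With quantile normalization the oxidative phosphorylation mean was 0.09 (adjusted p = 0.228). Mitochondrial import and chaperones had a mean of 0.094 (19 of 33 higher, adjusted p = 0.543) and passed with library weights (0.196, adjusted p = 0.00894) and without the unnumbered control (0.247, adjusted p = 0.0179) or S1pr1-null 1 (0.227, adjusted p = 0.00418). These calls used the preset correlation, and with all 6 libraries and an estimated correlation the adjusted p was 0.993. Mitochondrial dynamics and biogenesis had -0.026 (19 of 36 higher, camera direction lower, adjusted p = 0.855).

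**Figure D3:**
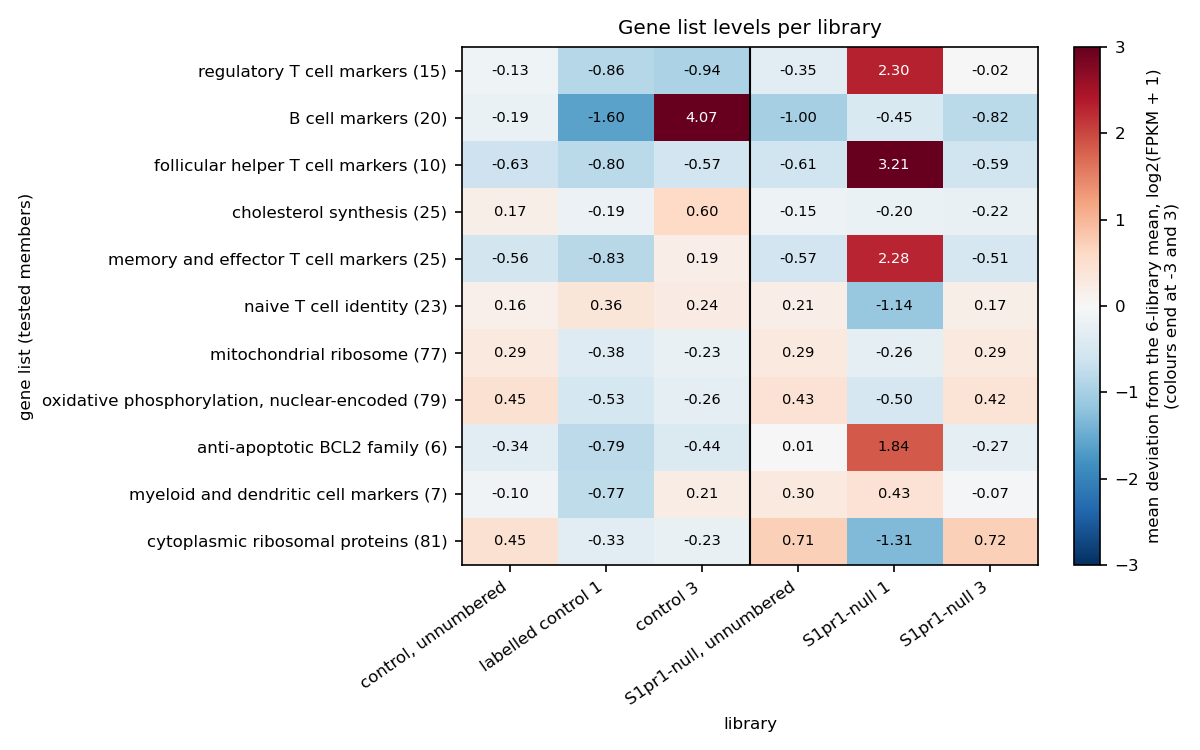
Mean deviation of each gene list (rows, with the number of tested members) from the mean of the 6 libraries (columns), in log2(FPKM + 1), for the 10 lists past the camera threshold and the cytoplasmic ribosomal proteins. The follicular helper list stands at 3.21 in S1pr1-null 1 and the B cell list at 4.07 in control 3, while the oxidative phosphorylation and ribosomal lists divide the libraries across the groups.

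Genes of cholesterol synthesis were lower in 21 of 25 (mean log2 difference -0.39, camera adjusted p = 3.14e-04; 0.979 with an estimated correlation). Ldlr, the receptor for low-density lipoprotein, had 3.52 to 10.1 FPKM in the controls and 1.47 to 2.93 FPKM in the S1pr1-null libraries. Hmgcr, the rate-limiting enzyme of the pathway, had 10.5 to 18.7 FPKM against 7.95 to 11.3 FPKM. Cyp51 had 4.06 to 23.3 FPKM against 1.51 to 5.76 FPKM. The highest list level was in control 3, the library with B cell transcripts (deviation 0.60). Without control 3 the mean was -0.183, just past the threshold at the preset correlation (camera adjusted p = 0.0498). Without control 3 and S1pr1-null 1, chosen after seeing the data, it was -0.178 and did not pass (adjusted p = 0.777). Without S1pr1-null 1 the mean was -0.382, near the full value but not past the threshold (adjusted p = 0.264). Anti-apoptotic BCL2 family genes were higher in 5 of 6 (mean 1.05, adjusted p = 0.0112; 0.979 with an estimated correlation). Bcl2a1b had 17.4 to 29.1 FPKM in the controls and 39.0, 140.7 and 36.4 FPKM in the S1pr1-null libraries, and Bcl2a1a and Bcl2a1d, near-identical copies whose reads are hard to part from it, moved with it at 41.8 and 67.3 FPKM in S1pr1-null 1. The list mean was 0.391 without S1pr1-null 1 (adjusted p = 0.054) and 0.915 without the library labelled control 1 (adjusted p = 0.121). Bcl2 itself, named after its values were seen, had 49.8, 65.6 and 100.7 FPKM in the controls and 58.6, 28.1 and 43.4 FPKM in the S1pr1-null libraries, and Bcl2l1 had 1706 FPKM in S1pr1-null 1 and 6.61 to 11.2 FPKM elsewhere.

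Lists tied to S1pr1 signalling and to migration did not pass with all 6 libraries. Sphingolipid metabolism and transport had 12 of 28 members higher (mean log2 difference -0.03, camera adjusted p = 0.867), with its most abundant members Sptssa at 101.4 to 143.7 FPKM in the controls and 91.2 to 133.7 FPKM in the S1pr1-null libraries and Cers2 at 45.2 to 61.9 FPKM against 38.6 to 73.2 FPKM. Naive T cell homing and adhesion had 9 of 22 higher (adjusted p = 0.867) and the targets of KLF2 and FOXO1 had 5 of 20 higher (mean -0.189, adjusted p = 0.289). The latter passed without the unnumbered control at the preset correlation (mean -0.359, adjusted p = 0.0482; 0.993 with an estimated correlation and all 6 libraries). Its mean was -0.07 without control 3. The most abundant members of both, Sell and Ccr7, were lowest in S1pr1-null 1, where Ccr7 had 51.9 FPKM and the other libraries 253.4 to 386.7 FPKM. Mitophagy had 14 of 24 higher (adjusted p = 0.458), with Park7 at 248.2 to 477.3 FPKM in the controls and 262.2 to 490.4 FPKM in the S1pr1-null libraries and Csnk2b at 57.4 to 100.9 FPKM against 76.4 to 99.7 FPKM. The list means were 0.11 for autophagy (adjusted p = 0.367), 0.06 for glycolysis (adjusted p = 0.681), 0.001 for fatty acid oxidation (median -0.02 and camera direction lower, adjusted p = 0.987), -0.07 for the tricarboxylic acid cycle (adjusted p = 0.434) and 0.34 for pro-apoptotic BCL2 family genes (7 of 7 higher, adjusted p = 0.0519). The pro-apoptotic list passed in 6 of the alternatives chosen before the data were examined (adjusted p = 0.0103 to 0.0434 at the preset correlation; 0.979 with an estimated correlation and all 6 libraries), among them without control 3 (mean 0.485) and without the unnumbered S1pr1-null library (0.535). Its mean was 0.2 without the unnumbered control (adjusted p = 0.25) and -0.011 without S1pr1-null 1. Cytoplasmic ribosomal proteins had a mean of 0.08 (adjusted p = 0.681; 0.993 with an estimated correlation). Their members move together (estimated correlation 0.929 against the preset 0.01), so the small p-values that follow, all at the preset, overstate the evidence. The list passed with library weights (0.628, adjusted p = 3.89e-19) and, in either direction, on leaving out 1 library. It was higher without S1pr1-null 1 (0.741, adjusted p = 7.33e-32) or the unnumbered control (0.322, adjusted p = 0.00318), and lower without the unnumbered S1pr1-null library (-0.258, adjusted p = 6.01e-05) or S1pr1-null 3 (-0.262, adjusted p = 5.47e-05). In a simulation of genes that vary independently, which real list members do not, a shift of 0.3 in the oxidative phosphorylation list had a camera adjusted p of 0.036 and a shift of 0.6 one of 1.8e-20.

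The libraries did not resemble each other by group. The mean correlation within groups minus that between groups was -0.0104 (exact permutation p = 0.7 over 10 splits, one-sided). The unnumbered control, the unnumbered S1pr1-null library and S1pr1-null 3 had pairwise correlations of 0.919 to 0.927, and no other pair exceeded 0.873. The first principal component held 43.1% of the variance and placed these 3 libraries at 34.8, 42.1 and 45.0, control 3 at 1.4, the library labelled control 1 at -34.1 and S1pr1-null 1 at -89.2. Between the 6 libraries, genes more than 4-fold above every other library numbered 166 in S1pr1-null 1, 56 in control 3 and at most 2 in each of the others, short RNA genes left out.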

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

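S1pr1 was lower in the S1pr1-null group under all 26 alternatives, from -4.23 to -1.63 on the log2 scale. It passed the threshold in 1 of them, chosen after seeing the data, without the library labelled control 1 and S1pr1-null 1 (-3.77, adjusted p = 0.00871). That library was left out for its S1pr1 level, so this p does not test the gene. Leaving out each library in turn gave -4.23 to -2.09. FPKM carry no counting error, which limits what can be said of low genes. The rules for duplicated and unlisted symbols had nothing to act on, so among the 26 alternatives they only repeat the main fit. The limma trend and robust settings do not enter camera, and the mitochondrially encoded share was not run.

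No gene was called higher under any alternative with all 6 libraries. The 2 lower genes became 0 with a pseudocount of 5 and 0 without a filter. Without each library in turn, 0 to 4 genes were higher and 1 to 8 lower, all short RNA genes. Of the alternatives chosen after seeing the data, leaving out short RNA genes and the library division as a term each gave 0 lower (111 and 351 genes at an unadjusted p under 0.05). Without control 3 and S1pr1-null 1, 4 were higher and 14 lower. Without the library labelled control 1 and S1pr1-null 1, 6 were higher and 9 lower. Either side of the library division alone gave 0 higher and 0 lower. Where 1 library stands for a group, its spread is assumed to be that of the others. The cause of these changes was not tested.

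The labels do not say that a number marks a shared animal or day, and the values do not pair all the libraries. Deviations from the group means correlated at 0.279 for the unnumbered pair, 0.363 for number 1 and 0.019 for number 3, with 5 of the 6 libraries correlated best with their own number and S1pr1-null 3 best with the unnumbered control. With the replicate block 0 genes were higher and 1 lower, Mir677 having an adjusted p of 0.0624. The numbered libraries alone with the block gave 3 higher and 6 lower, and 4 lists that had not passed did so there at the preset correlation: the targets of KLF2 and FOXO1 (-0.373, adjusted p = 0.0338), T cell activation (0.487, 0.0136), the cell cycle (0.403, 0.0251) and T cell maturity (-0.541, 0.0364).

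The 10 lists became 0 with an estimated correlation and 0 with fry. With library weights the naive (-0.182), memory (0.094), follicular helper (0.389) and cholesterol (-0.372) means were not past the threshold, nor without a filter on low values the anti-apoptotic (0.925) and myeloid (0.176) means. The same held for the myeloid mean with a filter at 5 FPKM (0.229) and the oxidative phosphorylation mean with quantile normalization (0.09). Lists that passed only in alternatives, all at the preset correlation, include the pro-apoptotic genes, in 6 chosen before the data were examined (adjusted p = 0.0103 to 0.0434), and the proteasome with a pseudocount of 5, no filter, or weights (0.143, 0.138 and 0.245). Weights also brought in ribosomal proteins (0.628) and mitochondrial import (0.196). Without each library in turn, 5 to 14 passed. The side of the division with the unnumbered libraries and S1pr1-null 3 gave 5, and the other side 16. At the preset correlation, the regulatory list passed all 18 planned settings, 2 repeating the main fit. It did not with the estimated 0.531 (adjusted p = 0.979) or fry (0.989). With 1 library left out, the mean turned in 2 of the 10 lists and in 29 of the 34 that had not passed, among them pro-apoptotic genes (-0.011) and T cell activation (-0.107) without S1pr1-null 1 and CD8 markers (0.561) without control 3. Of the 10, B cell markers turned without control 3 (0.377) and without it and S1pr1-null 1 (0.171). Memory markers did so without S1pr1-null 1 (-0.125) and without it and the library labelled control 1 (-0.41), where follicular helper markers had -0.055. Ribosomal proteins, not among the 10, passed at -0.258 and -0.262 without the unnumbered S1pr1-null library and S1pr1-null 3, and -0.381 with the division as a term, where oxidative phosphorylation had -0.066. Means with 1 library left out ran from -2.694 to 0.377 for B cell markers, -0.125 to 1.276 for memory markers and -0.262 to 0.741 for ribosomal proteins. On the first side of the division alone, means turned for naive identity (0.027), oxidative phosphorylation (-0.027), regulatory markers (-0.042) and T cell maturity (0.344). On the other side, they turned for oxidative phosphorylation (-0.105), ribosomal proteins (-1.03), the NF-kappaB pathway (0.733) and erythroid markers (-2.834).

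Of 59 genes named beside S1pr1, 8 turned somewhere, none of them past the threshold. Sell had 0.37 without S1pr1-null 1, 0.48 without it and control 3, 0.24 without it and the library labelled control 1, and 0.35 on the first side alone. Ccr7 had 0.27, 0.14 and 0.22 in the first 3 of these and 0.06 with library weights. Sptssa had 0.12 with weights, 0.11 without control 3, 0.15 without S1pr1-null 1, 0.29 and 0.04 without the 2 pairs, and 0.19 on the first side. Cers2 had 0.01 with the numbered block, 0.07, 0.10 and 0.05 without control 3, the unnumbered S1pr1-null library and S1pr1-null 3, 0.12 with the division as a term and 0.42 on the second side. Csnk2b had -0.07 without the library labelled control 1 and -0.05 on the first side, where Tnfrsf4 had -0.17, Tdrp 0.08 and Atpif1 -0.31. With 1 library left out, the log2 differences ran from -2.08 to 0.37 for Sell, -1.13 to 0.27 for Ccr7, -0.14 to 0.15 for Sptssa, -0.35 to 0.10 for Cers2 and -0.07 to 0.33 for Csnk2b.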

Other observations

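All tests in this part were chosen after the results were seen, except the correction for transcript length and GC content, whose bounds were set before it was run. The library labelled control 1 was the only one with transcripts of the Y chromosome, with Ddx3y at 21.7 FPKM, Eif2s3y at 26.9 FPKM, Kdm5d at 3.63 FPKM and Uty at 4.14 FPKM, each at most 0.0293 FPKM elsewhere. Xist had 0.00762 FPKM there and 3.26 to 13.4 FPKM in the other 5 libraries. Control 3 had Cd74 at 6141 FPKM, H2-Aa at 1191 FPKM, Cd19 at 59.1 FPKM and Cd8b1 at 180.7 FPKM.

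The real split called 2 genes and 10 lists. Over the 10 splits of the 6 libraries into 3 and 3, 9 called as many genes, the highest of the others 718, and 9 called as many lists, the highest of the others 15. With 10 splits no share under 0.05 can be reached.

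The split with 718 genes sets the unnumbered control, the unnumbered S1pr1-null library and S1pr1-null 3 against the library labelled control 1, control 3 and S1pr1-null 1, and points to a structure of the samples other than the genotype, since each side holds both groups. Ets1, a transcription factor of lymphocytes, had 93.3, 93.3 and 86.4 FPKM on the first side and 606.7, 579.0 and 561.9 FPKM on the second, while Btg1, an antiproliferative gene, had 597.2 to 641.0 FPKM against 206.9 to 235.9 FPKM. Sequencing depth is argued against as far as the estimate of relative depth holds, since the second side holds the deepest library (1.181 relative to the unnumbered control) as well as the shallowest. That estimate assumes FPKM scaled to the mapped fragments, and the normalization option is not given. The sides did differ in genes at 1 FPKM or more, 8625 to 8886 on the first and 9144 to 10190 on the second. The 417 genes lower on the second side had a median transcript length of 803 bases and the 301 higher ones 2606. A trend on length and GC content alone held 14.6% of the variance over genes of the difference between the sides. Removing a smooth trend on length, GC content and level left 271 genes past the threshold, 237 of them among the 718. Since level was removed too, the fall from 718 cannot be credited to length and GC content alone. A length and GC trend may account for part of the split and the rest stays open. The labels give no library batch, so a difference in preparation was not tested, nor was any biological explanation.

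S1pr1-null 1 carried a non-naive profile, with Sell at 4.89% and Klf2 at 48.2% of the lowest other library. Tigit had 380.2 FPKM there, Lag3 180.4 FPKM, Ccl5 549.7 FPKM and Foxp3 73.0 FPKM. Whether the low S1pr1 of this library comes from the deletion or from its cell state cannot be told apart. Non-naive cells that gave only a minority of the RNA are argued against: 11 of 23 naive list members lay more than 2-fold below the lowest other library, and 0 did so in any other library. The remaining members did not, among them Tcf7 at 107% and Il7r at 189% of the lowest other library. FPKM are shares of RNA, so these values do not give the share of cells. A library mostly of antigen-experienced T cells remains a candidate explanation, since 20 of 25 memory and effector members were highest in it, although the gate would exclude such cells. The same library had Bcl2l1 at 1706 FPKM, 153 times the highest other library. The mouse growth hormone gene Gh had 348.3 FPKM there against at most 2.95 FPKM elsewhere. Growth hormone 3' ends are used in expression vectors, but whether such a sequence gave the reads assigned to mouse Gh is not known. A Bcl2l1 transgene may be the source of both, and values per gene, which do not show the structure of a transcript, keep this open. The gene column of all 6 tables was headed Bcl2Tg_Ctrl_1, a name that the labels do not explain and that, being in every table, sets no library apart.

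The library labelled control 1 had S1pr1 at 10.1 FPKM, 16.2-fold below the lower of the other controls. Dropout in a shallow library is argued against, since of 247 genes at 100 to 300 FPKM in both other controls 2 (0.81%), S1pr1 and Mir8094, lay at least 16-fold below them. A cell state with low Klf2, the transcription factor that drives S1pr1, is argued against by Klf2 at 124% and Sell at 83.2% of the lower of the other controls. An S1pr1-null library with a wrong label stays open: over 100 genes chosen without it, it lay at 0.775 between controls (0) and S1pr1-null (1), but the unnumbered control lay at 0.834 and S1pr1-null 1 at -0.084 when treated alike, so these genes do not place a library. Reads over the floxed part, or donor genotypes, would be needed to decide.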
